A study of Homo sapiens with 5 samples.

How the data were processed

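Gene expression was measured by 3' end RNA sequencing in 5 libraries of SW480, an established human colorectal cancer cell line. The cells expressed dCas9-KRAB, a nuclease-dead Cas9 fused to a transcriptional repressor domain, which lowers transcription where a guide RNA places it (CRISPR interference). Per the labels' protocols, cells received control guides or a guide against AKAP12, and RNA was extracted 48 hours after seeding. The titles and one label field call the same groups shControl and shAKAP12, so the labels name 2 different silencing methods, and the treatment protocol was followed here for the description. Libraries were made with a QuantSeq forward kit, which primes on poly(A) and reads the 3' part of transcripts, per the labels' protocols. There were 2 control and 3 knockdown libraries.

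The deposited count of each gene in each library is a whole number of reads. Per the file headers, the authors counted reads over exons by gene with featureCounts 1.6.2, with reads that overlap several genes counted for each of them and no strand option. Reads from overlapping or antisense genes therefore cannot be told apart in these counts. Alignment to hg38 used STAR 2.7, per the submitters' processing notes. Read trimming and the use of molecular identifiers are not given in the sources used here, so counting intervals cover counting error only. The authors' deposited table of the comparison holds, per its header, a mean signal, a log2 fold change, its standard error and test statistic (a score), and p-values. DESeq2 1.22 is named in the submitters' processing notes. The model and the direction of the fold change are not stated, and the direction was read from its correlation with the fitted values.

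The files hold 26485 genes. Total counts per library were 4935096 and 8670141 in the controls and 9311026, 6890868 and 7763190 in the knockdown. A count of 0 allows up to 0.608 CPM (counts scaled to the library total) in control 1 and 0.322 to 0.435 CPM in the other libraries, taking 3 counts as the limit. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. No pair of libraries agreed within sampling noise: the chi-square statistic per degree of freedom between libraries was 5.50 to 9.13 within the knockdown group and 109.3 between the controls.

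Genes were filtered with filterByExpr (minimum count 10), which left 14536, and scaled with TMM factors. Groups were compared with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), two-sided, without covariates, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors (SE) are the absolute log2 fold change divided by the square root of the F statistic. Fold changes are knockdown over control, and CPM values are TMM-scaled. SD is given over the 3 knockdown libraries, and both values are given for the controls. With 2 libraries against 3, an exact permutation test of one gene cannot go below p = 0.1.

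A set of 22 gene lists was written from textbook knowledge before the data were examined, among them markers of stromal and blood cells. Of these, 21 were tested with camera (limma 3.58.1) at a preset correlation of 0.01, on log2 CPM with a prior count of 2. The list of 13 mitochondrially encoded genes had no member in the count files. Members past the threshold were counted over all genes tested and over the list alone. Genes with a start within 500 kb of AKAP12 were read from the coordinates in the count files. Transcript GC content was that of the longest GENCODE release 29 transcript of each gene, with a value for 97.4% of tested genes.

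Named genes were chosen by a rule fixed before the data were examined. They were AKAP12, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with a mean log2 CPM of at least 4 and no overlap between groups, up to 4 members per list with the smallest p, RBMS1 and SDCBP, and the tested genes near AKAP12. TPX2, PTMA, ACTN4, UQCRQ, the complex I and ribosomal protein genes named as lower, and the genes named in the other observations were chosen after their values were seen. Alternatives were DESeq2 1.42.0, limma-voom, RLE scaling, library size only, no filter, a stricter filter (5 CPM in at least 2 libraries), the replicate number as a block, each library left out in turn, an estimated correlation in camera, and fry. Removing TERT and short RNA genes, and GC-dependent offsets (a smooth with span 0.2), were added after the data were seen. The procedure was tested on simulated counts of 14295 genes with the real means and library sizes. In the comparison of knockdown with control it recovered 55% of 100 genes changed 4-fold and 3.03% of 99 genes changed 2-fold. It also called 9 of 14096 unchanged genes. Set against the few genes recovered, these false calls were a larger share of all calls than the nominal rate of the adjusted threshold. With so few changed genes the adjusted threshold was stricter than in the real comparison, so the recovered shares do not carry over to it. The share of false calls in the real comparison is not known from this simulation.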

Results

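The data were gene counts from 5 3' end RNA libraries of SW480 cells carrying the CRISPR interference repressor, 2 with control guides and 3 with a guide against AKAP12. Total counts lay between 4935096 and 9311026, and 17112 to 18515 genes had at least 1 read. The design holds 1 comparison, which asks how the expression of AKAP12 and of other genes differs between knockdown and control cells.

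AKAP12 encodes a scaffold protein that binds protein kinase A and protein kinase C. The gene lies on chromosome 6 from 151239999 to 151358561 (hg38, plus strand). Its level was 2870 and 1550 CPM in the control libraries and 1077 ± 76.4 CPM (SD, n = 3) in the knockdown libraries, which were all below both controls. The fitted level was 2.05-fold lower in the knockdown, with a log2 fold change of -1.04 (SE 0.31) and an edgeR adjusted p of 0.0513, just outside the threshold. The value rested on control 1, since it was -0.52 without that library and -1.42 without control 2. With 1 control left, the spread came from the knockdown libraries alone, so no p-value is given for those fits. Adjusted p values over the other alternatives ran from 0.0114 (DESeq2) to 0.298 (edgeR with the replicate number as a block).

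**Figure D1:**
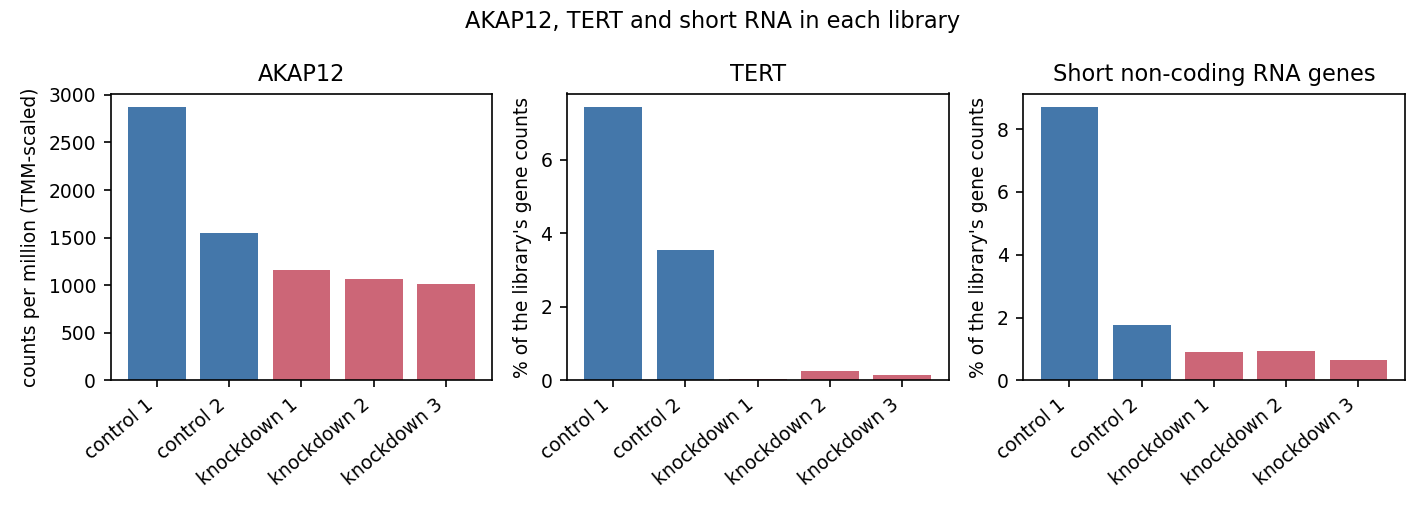
Bars give one library each (blue, control; red, knockdown) for AKAP12 in TMM-scaled CPM and for TERT and short non-coding RNA genes in percent of the library's gene counts. AKAP12 stood at 2870 and 1550 CPM in the controls and at 1008 to 1159 CPM in the knockdown libraries, and TERT took 7.43% and 3.54% of the control counts.

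The control libraries differed from each other more than the knockdown libraries did. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.90 between the controls and 0.98 for each knockdown pair. Control 1 reached 0.79 to 0.81 with the knockdown libraries and control 2 reached 0.92 to 0.93. TERT, the catalytic subunit of telomerase (chromosome 5, 1253172 to 1295047), held 366479 and 306715 reads in the controls against 4198, 17172 and 12480 in the knockdown. Short non-coding RNA genes took 8.70% and 1.76% of control counts and 0.655% to 0.949% of knockdown counts. Ribosomal protein genes took 5.37% and 8.44% of control counts and 9.31% to 9.68% of knockdown counts. The 10 most abundant genes took 20.2% and 9.13% against 5.41% to 5.65%.

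In the knockdown, genes for a tetraspanin (CD9), an actin-binding protein (PFN1), a small-subunit ribosomal protein (RPS7) and the mitochondrial ADP/ATP carrier (SLC25A5) rose, while TERT and the short non-coding RNA SNAR-E fell. CD9 (chromosome 12, 6200316 to 6238271) rose 18.6-fold, from 19.1 and 12.8 CPM to 294.3 ± 62.9 CPM (SD, n = 3; log2 fold change 4.22, SE 0.34, edgeR adjusted p = 0.0124). RPS7 (chromosome 2, 3575263 to 3580919) rose 20.2-fold, from 8.82 and 23.2 CPM to 330.5 ± 62.9 CPM (SD, n = 3; edgeR adjusted p = 0.0131). Its log2 fold change of 4.34 was 3.83 without control 1 and 5.22 without control 2. TERT fell from 89771 and 35177 CPM to 1421 ± 940 CPM (SD, n = 3), with a log2 fold change of -5.46 (SE 0.81, edgeR adjusted p = 0.0152). Whether these reads come from native TERT mRNA cannot be told from gene counts. SNAR-E, a short non-coding RNA transcribed by RNA polymerase III (chromosome 19, 46830585 to 46830704), fell from 71750 and 3517 CPM to 1277 ± 301 CPM (SD, n = 3; log2 fold change -4.88, SE 1.08, edgeR adjusted p = 0.0270).

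Among the other genes with the largest rises, PFN1 had a log2 fold change of 4.24, SLC25A5 of 4.10, the mitochondrial ribosomal protein gene MRPL34 of 3.99 and the TWEAK receptor gene TNFRSF12A of 3.92. Without control 1 these were 3.53, 3.47, 3.53 and 3.21, and without control 2 they were 5.92, 5.39, 4.89 and 6.33. MIR1244-1, MIR1244-2, MIR1244-3 and MIR1244-4 held identical counts (log2 fold change 5.33, 4.70 without control 1, and without control 2 a ratio of 175 with an exact 95% counting interval of 59.9 to 850, from 3 reads in control 1) on sequence shared with PTMA, so they are one uncertain measurement. PTMA itself had a log2 fold change of -0.72 (edgeR adjusted p = 0.0722). CAPN12 (4.16, and 3.45 without control 1 or 5.69 without control 2) overlaps ACTN4 (0.14, edgeR adjusted p = 0.814) and GDF9 (4.04) overlaps UQCRQ (0.50, edgeR adjusted p = 0.230), and their reads could not be assigned to one gene of each pair. SLC25A5 overlaps SLC25A5-AS1. Some genes named below overlap another gene too, among them KRT8 (KRT18), PRKAR1B (DNAAF5), NDUFA1 (RNF113A), SDHC (CFAP126), TNFRSF10B (RHOBTB2) and PCNA (PCNA-AS1). Exons of 24.1% of the changed genes and 21.9% of all tested genes overlapped another gene.

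The other large falls were in the small nucleolar RNA genes SNORD57 (-4.60), SNORD89 (-3.82) and SNORD50A (-3.48), in SNAR-H (-4.38) and SNAR-G1 (-3.34), and in the histone genes HIST1H4H (-4.06), HIST1H2AJ (-3.69) and HIST2H2AC (-3.42). GSTZ1, an enzyme of tyrosine breakdown, was at -3.61, and SENP3, a SUMO protease gene whose exons overlap the read-through gene SENP3-EIF4A1, was at -3.31. SNAR and histone genes are multigene families with similar copies, so the split of reads among members is uncertain. These falls shrank without control 1: SNAR-E to -1.46, SNORD57 to -1.77, SNAR-H to -1.19, HIST1H4H to -1.67, SNORD89 to -1.79, HIST1H2AJ to -1.66, GSTZ1 to -2.04, SNORD50A to -0.69, HIST2H2AC to -1.57, SNAR-G1 to -1.49 and SENP3 to -1.39. TERT was at -4.63 without it. Without control 2 the same 11 genes had larger falls, from -4.12 (SENP3) to -5.81 (SNAR-E). By limma-voom 4 of these genes missed the threshold, SNORD57 (adjusted p = 0.0576), HIST1H4H (0.0597), SNORD50A (0.0782) and SNAR-H (0.0939).

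**Figure D2:**
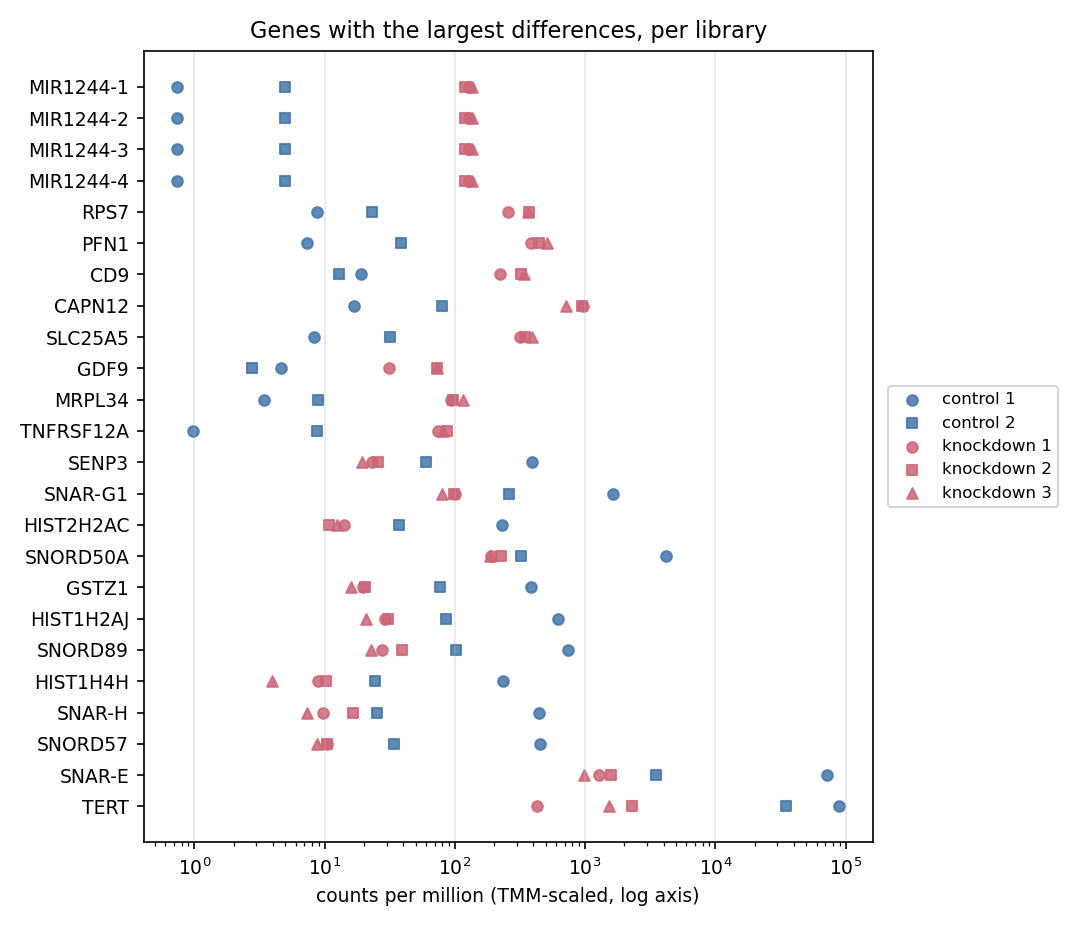
Points give TMM-scaled CPM on a log axis for each library (blue, control; red, knockdown) of the 12 genes with the largest rise and the 12 with the largest fall. In each gene the knockdown libraries lie on one side of both controls, and control 1 lies above control 2 in all 12 genes that fell (for TERT, 89771 against 35177 CPM).

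Over all genes, 3282 of 14536 passed the edgeR threshold, 1624 higher and 1658 lower in the knockdown, and 2670 of these differed at least 2-fold. Without a composition factor, which shifted the median log2 fold change by 0.20, the split was 1668 higher and 982 lower. The groups did not overlap in 60.1% of tested genes. Chance gives 20% for a single gene, but genes are not independent. Any difference between the libraries, whatever its source, can therefore move the share over all genes away from 20%. Fits with 1 control left took their spread from the knockdown libraries alone. Their counts of calls, also in the lists below, leave out the difference between the controls and are not comparable with the main counts. The count was 0 without any one of the knockdown libraries, where 3774 to 4109 genes had an unadjusted edgeR p under 0.05.

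Nuclear-encoded subunits of the oxidative phosphorylation complexes were higher as a list. Of 40 members, 11 rose and 4 fell (17 and 4 adjusted over the list alone), the median log2 fold change was 0.75, and camera gave an adjusted p of 0.00341 with the preset correlation and an adjusted p = 0.889 with an estimated correlation. The median was 0.56 without control 1 (22 up, 7 down) and 1.20 without control 2 (31 up, 5 down). Complex I subunit NDUFB3 rose by a log2 fold change of 3.31 (SE 0.28), NDUFA1 rose by 2.17, and the succinate dehydrogenase subunits SDHC and SDHB rose by 2.54 and 2.21. NDUFV1, NDUFS7, NDUFA13 and NDUFB10, also of complex I, fell. Ribosomal protein genes had 12 members up and 3 down of 47 (18 and 5 adjusted over the list alone), a median of 0.93 and a camera adjusted p of 0.0356, with an adjusted p = 0.889 with an estimated correlation. Without control 1 the median was 0.45, and without control 2 it was 1.52. RPL30 rose by 2.12, RPL7A by 1.57 and RPL4 by 1.56, whereas RPS9, RPL35 and RPL8 fell.

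The other 19 tested lists did not pass, with camera adjusted p values from 0.128 to 0.811. Their counts of members up and down are to be read against the 3282 of 14536 tested genes called by edgeR. A list whose share of called members is near that of all genes shows no response of its own. The closest was the unfolded protein response and ATF4 list, where 9 of 32 members rose and 3 fell (9 and 3 adjusted over the list alone, 11 and 5 without control 1, 21 and 6 without control 2). The mitochondrial folate enzyme gene MTHFD2 rose by 1.87, MANF by 2.43 (3.35 without control 2) and TRIB3 by 1.10, and SDF2L1 fell by 1.68 (-1.09 without control 1). In the TGF-beta list 7 of 27 rose and 3 fell (8 and 3 adjusted over the list alone, 11 and 5 without control 1, 12 and 5 without control 2), with TGIF1 up by 1.47, NEDD9 at -0.86 and the ligand gene TGFB1 at -2.21 (-1.30 without control 1). By library size only NEDD9 missed the threshold (edgeR adjusted p = 0.0547).

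Cell cycle genes moved both ways. In the DNA replication and E2F list 11 of 33 rose and 5 fell (12 and 7 adjusted over the list alone, 13 and 8 without control 1, 16 and 11 without control 2), with the flap endonuclease gene FEN1 at 2.41 (3.39 without control 2), the sliding clamp gene PCNA at 2.31 (2.96 without control 2), the primase gene PRIM1 at 1.64 and DUT at 1.29, all higher. In the mitosis and G2/M list 7 of 32 rose and 1 fell (8 and 3 adjusted over the list alone, 14 and 6 without control 1, 16 and 7 without control 2), with the centromeric histone gene CENPA at 1.93, BIRC5 at 1.32 and KIF23 at 1.06. UBE2C was at 2.05 (1.45 without control 1, 3.13 without control 2), and the member that fell was the spindle assembly factor gene TPX2 at -0.86. Of 25 p53 targets, 4 rose and 2 fell (5 and 2 adjusted over the list alone, 8 and 6 without control 1, 9 and 5 without control 2), among them CCNG1 at 1.59, TNFRSF10B at 1.66 (2.37 without control 2), TIGAR at 1.09 and BAX at -2.14 (-1.09 without control 1, -2.75 without control 2).

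Glycolysis genes were split by member. In the hypoxia and glycolysis list 7 of 29 rose and 7 fell (11 and 8 adjusted over the list alone, 11 and 9 without control 1, 12 and 10 without control 2). GAPDH fell by a log2 fold change of 2.63 (-1.48 without control 1, -3.27 without control 2), the pyruvate kinase gene PKM by 1.42 and ALDOA by 1.17, while the lactate dehydrogenase gene LDHA rose by 1.54. In cholesterol synthesis 3 of 25 rose and 2 fell (3 and 2 adjusted over the list alone, 7 and 2 without control 1, 13 and 3 without control 2), with INSIG1 at 1.62 and CYP51A1 at 1.10, and NSDHL at -1.63 and MVD at -1.24. With GC offsets, CYP51A1 (edgeR adjusted p = 0.0522) and MVD (0.0615) missed the threshold, as did MVD by library size only (0.0546).

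In the cAMP and CREB list 4 of 23 rose and 1 fell (4 and 1 adjusted over the list alone, 6 and 1 without control 1, 8 and 5 without control 2). KLF2 rose from 0.980 and 0.918 CPM to 13.6 ± 2.18 CPM (SD, n = 3; edgeR adjusted p = 0.0124), JUNB was at 2.59 (3.65 without control 2), and the phosphatase gene DUSP1 was at 3.98 (3.36 without control 1) with 0 and 7 control reads. Without control 2, DUSP1 was at least 11.4-fold higher, counted against a floor of 3 reads in control 1. NR4A1 rose from 2 and 1 control reads to 2.91 ± 0.485 CPM (SD, n = 3), a ratio of 12.6 with an exact 95% counting interval of 4.15 to 62.6. Its ratio was 25.8 (4.49 to 1032) without control 1 and 6.03 (1.61 to 50.7) without control 2. In the immediate early and stress list 7 of 31 rose and 4 fell (7 and 4 adjusted over the list alone, 11 and 7 without control 1, 13 and 10 without control 2), with HSPA1B at 1.54, SRXN1 at 1.33 and the heme oxygenase gene HMOX1 at -1.61. In the YAP/TEAD and SRF list 5 of 33 rose and 5 fell (5 and 6 adjusted over the list alone, 10 and 10 without control 1, 12 and 9 without control 2), with AJUBA at 2.89, LATS2 at 1.29 and the actin cross-linker gene FLNA at -1.47. FOXF2 rose from 0 and 1 control reads to 5.77 ± 0.932 CPM (SD, n = 3), a ratio of 73.2 with an exact 95% counting interval of 12.9 to 2910. Its ratio was 49.8 (8.80 to 1982) without control 1, and without control 2 it was at least 7.78-fold higher against the same floor. In the Wnt list 5 of 25 rose and 6 fell (9 and 6 adjusted over the list alone, 9 and 8 without control 1, 13 and 8 without control 2), with the Wnt deacylase gene NOTUM at 3.77 (without control 2 a ratio of 25.3, counting interval 6.96 to 210), BAMBI at 1.61, PTPRO at -1.75 and BMP4 at -1.40 (-0.84 without control 1).

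Among kinase A and C subunits and anchoring proteins, 0 of 30 rose and 4 fell (0 and 2 adjusted over the list alone, 2 and 8 without control 1, 1 and 11 without control 2). PRKAR1B, a regulatory subunit of protein kinase A, was at -1.94 (-1.31 without control 1), the inhibitor gene PKIG at -1.13, AKAP8L at -0.92 and AKAP8 at -0.89 (-0.57 and -0.52 without control 1). In the NF-kB and cytokine list 2 of 23 rose and 1 fell (1 and 1 adjusted over the list alone, 4 and 4 without control 1, 7 and 9 without control 2), with SOD2 at 1.16, NFKBIA at 1.20 (1.79 without control 2) and IL32 at -1.13. In the interferon list 2 of 29 rose and 3 fell (0 and 0 adjusted over the list alone, 1 and 5 without control 1, 8 and 6 without control 2), with IRF7 at 2.65 (without control 2 a ratio of 11.7, exact 95% counting interval 3.17 to 97.3), HERC6 at -1.49, USP18 at -1.93 and OAS3 at -1.30 (-0.74 without control 1). By library size only the calls of AKAP8 (edgeR adjusted p = 0.0691), AKAP8L (0.0839), NFKBIA (0.0552), HERC6 (0.0584) and USP18 (0.0728) were lost, and AKAP8L also missed the threshold by limma-voom (adjusted p = 0.0560) and with GC offsets (edgeR adjusted p = 0.118).

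Of 29 mesenchymal genes, 1 rose and 4 fell (0 and 4 adjusted over the list alone, 6 and 10 without control 1, 12 and 9 without control 2). The fibronectin gene FN1 fell from 2388 and 883 CPM to 371 ± 59.4 CPM (SD, n = 3; log2 fold change -2.14, edgeR adjusted p = 0.0217, -1.25 without control 1). ZEB2 was at -1.59 (-1.04 without control 1), MMP14 at -1.30 and FBN1 at -0.90. Of 25 epithelial genes, 1 rose and 2 fell (1 and 1 adjusted over the list alone, 4 and 2 without control 1, 10 and 8 without control 2), with the keratin gene KRT8 at 1.78, PKP3 at -1.64 and DSG2 at -1.44 (-0.58 without control 1). No member of the intestinal differentiation list passed (15 tested, 0 adjusted over the list alone). Its median log2 fold change was -0.48, against -0.15 without control 1 and -0.83 without control 2. Stromal markers had 0 of 15 up and 2 down (0 and 2 adjusted over the list alone, 0 and 5 without control 1, 7 and 3 without control 2), COL6A3 at -1.68 (-0.99 without control 1) and PDGFRA at -1.08. Blood and immune markers had 0 of 19 up and 3 down (0 and 0 adjusted over the list alone, 0 and 4 without control 1, 4 and 3 without control 2), CD68 at -0.96, CSF1R at -1.41 (-0.77 without control 1) and CD3D at -1.82. Some of these calls did not hold in other fits. CD3D missed the threshold by DESeq2 (adjusted p = 0.0730) and without a filter (edgeR adjusted p = 0.0826), and was at -1.53 without control 2. CSF1R missed it by limma-voom (adjusted p = 0.0564) and with GC offsets (edgeR adjusted p = 0.0570). DSG2 missed it by limma-voom (adjusted p = 0.0874), and MMP14 with GC offsets (edgeR adjusted p = 0.0575). By library size only, CD3D, CSF1R, CD68, DSG2, FBN1 and MMP14 had edgeR adjusted p values from 0.0537 to 0.0822. Median, mean and camera direction differed in sign for the interferon, epithelial and blood lists.

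**Figure D3:**
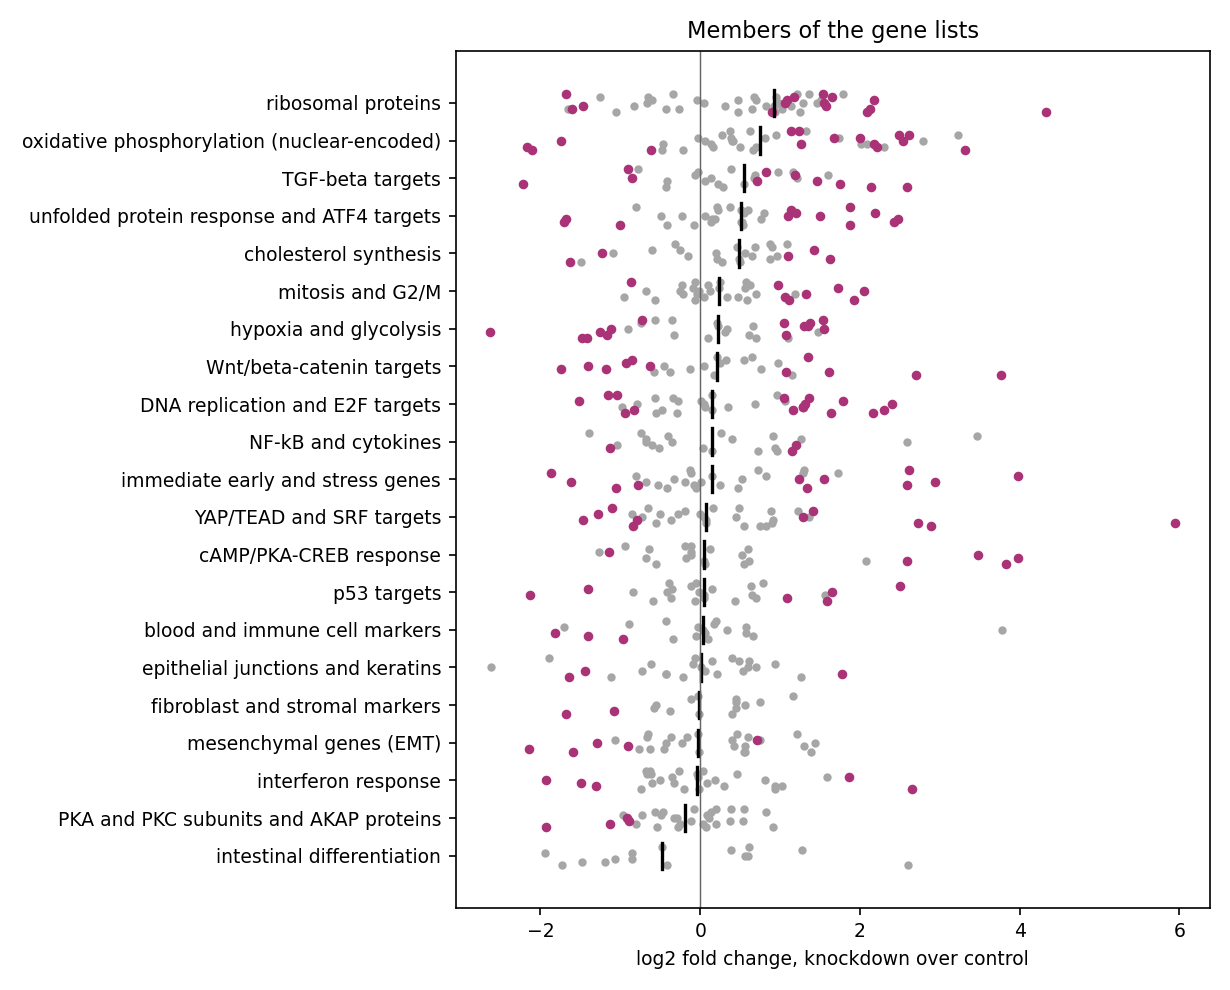
Each point is the fitted log2 fold change, knockdown over control, of one member of a gene list, purple where it passed the edgeR threshold, with a black line at the list's median. The medians of the ribosomal protein list (0.93) and the oxidative phosphorylation list (0.75) are the highest of the 21 lists.

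Of the genes linked to AKAP12 in the field, SDCBP, which encodes the adaptor protein syntenin-1, rose 2.98-fold, from 18.6 and 16.7 CPM to 52.6 ± 6.71 CPM (SD, n = 3; log2 fold change 1.58, SE 0.23, edgeR adjusted p = 0.0146). The RNA-binding protein gene RBMS1 was at 46.3 and 72.9 CPM in the controls and 65.0 ± 6.58 CPM in the knockdown (SD, n = 3; log2 fold change 0.12, SE 0.25, edgeR adjusted p = 0.748). Its log2 fold change was -0.16 without control 1 and 0.48 without control 2, so its direction rested on which control was used.

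Genes near AKAP12 were examined because CRISPR interference can act on neighbouring promoters. None of 6 tested neighbours passed the edgeR threshold, and 3 had an unadjusted p under 0.05. Over all 14536 tested genes, 5890 had an unadjusted edgeR p under 0.05, so 3 of 6 does not set the neighbours apart. ZBTB2 (chromosome 6, 151364115 to 151391700) had a log2 fold change of 1.09 (edgeR adjusted p = 0.0540), ARMT1 of 1.05 (0.0506), RMND1 of 0.81, CCDC170 of -0.41, MTHFD1L of 0.00 and the estrogen receptor gene ESR1 of -1.08 (edgeR adjusted p = 0.113). By other tools, DESeq2 called 2 of them and limma-voom 1.

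The authors' deposited table gave nearly the same fold changes. The DESeq2 fit by group used here gave the deposited values for AKAP12 (-1.06223, SE 0.343464) and CD9 (4.19872). The agreement is therefore a second fit of the same counts and not independent support. Spearman's rho across 14536 genes was 0.9996 against the fitted values, with knockdown over control as the matching direction. The authors' deposited table lists AKAP12 at -1.06 (adjusted p = 0.0124), SDCBP at 1.56 (adjusted p = 8.6e-06) and RBMS1 at 0.11 (adjusted p = 0.838). The authors' deposited table gives 4074 genes an adjusted p under 0.05, 2035 higher and 2039 lower. Of the 3282 genes called by edgeR, 3235 were also called in the authors' deposited table, all with the same sign, and 766 tested genes were called only there.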

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

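Removing TERT and short RNA genes and the GC-dependent offsets were chosen after the data were seen. Of the 3282 genes called by edgeR, none changed sign in any alternative fit in which it was tested. In all 3282 the groups did not overlap, so leaving out a library could hardly turn a sign. The other fits used the same libraries, so this count is no test of the direction. The counts of calls ran from 2650 to 4164 over DESeq2, limma-voom, other scalings and other filters, with 982 lower genes by library size only. Leaving out one library gave 0 to 8811 calls (0 to 4625 higher, 0 to 4186 lower). The 0 arose without knockdown 1, 2 or 3, where both groups had 2 libraries, and 4015, 4109 and 3774 genes had an unadjusted edgeR p under 0.05. With 1 control left, that library was assumed to vary like the knockdown libraries. A fit with the replicate number as a block called 210 genes (185 higher, 25 lower). Only 2 numbers are shared, and the deviations of same-numbered libraries correlated at -0.05 and -0.08. With 2 controls their deviations are mirror images set by the large difference between them. These values therefore cannot show whether a number marks a shared culture or day, which the labels do not say. AKAP12 was -0.93 with the block (edgeR adjusted p = 0.298) and -1.42 to -0.52 with one library left out. It passed the threshold at -1.06 by DESeq2, -0.98 by limma-voom, -0.996 without a filter, -1.06 with the stricter filter, -1.04 without TERT and short RNA genes and -1.16 with GC offsets. Its depth was not the limit, with 7936 to 13513 reads. Of genes near AKAP12, the number called was 2 by DESeq2, 1 by limma-voom, 2 by library size only, 2 without a filter, 1 with the stricter filter, 1 without TERT and short RNA genes, and 0 to 3 with one library left out. Among gene lists, 1 passed by library size only, 1 to 2 with one library left out, 0 with an estimated correlation and 0 by fry (lowest adjusted p 0.0539). RBMS1 reversed to -0.10 with GC offsets and ran from -0.16 to 0.48 with one library left out, reversed without control 1. MTHFD1L reversed to -0.013 (DESeq2), -0.00018 (limma-voom), -0.037 (RLE), -0.016 (stricter filter), -0.0028 (without TERT and short RNA genes) and -0.033 (GC offsets), and ran from -0.033 to 0.039 with one library left out, reversed without control 1 and without knockdown 1. Lists that passed in no fit changed camera direction in 12 of 293 list results, where the medians were 0.17 (epithelial) and 0.30 (stromal) without a filter, -0.058 (epithelial) with GC offsets and -0.18 (NF-kB) with the stricter filter. The other changes came with one library left out. The medians then ran from -0.37 to 0.25 (interferon), -0.14 to 0.33 (mesenchymal), -0.11 to 0.20 (epithelial), -0.058 to 0.51 (stromal) and -0.20 to 0.044 (blood). In each of these lists the camera direction turned without control 2. The medians ran from -0.83 to -0.15 (intestinal) and -0.055 to 0.30 (p53), where the camera direction turned without control 1. For NF-kB they ran from 0.072 to 0.32, and the camera direction turned without knockdown 2. In those fits the medians of the intestinal, p53 and NF-kB lists kept the sign of the main fit. The cause of the changes in camera direction was not tested. Of 97 named genes that passed, the fold moved over 1.5 times in 32 without control 1 and in 35 without control 2.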

Other observations

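The families described next, the axis test and its subset of abundant genes, the library-size test of a few abundant genes, the test of control 1 alone, and the tests of genomic DNA and of the SNAR-E to TERT ratio were chosen after the results were seen. The fits with GC offsets and without TERT and short RNA genes were also added after the data were seen, but their bounds, and those of the GC correlation and the AKAP12 test, were set before their own results.

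Of 13 families outside the fixed lists that were tried, 7 passed camera with the preset correlation, and each of the 7 had an adjusted p = 0.432 with an estimated correlation. Since the families were chosen after the results were seen, their camera p-values only describe these data and carry no error rate. Of 12 genes for the Sec61 channel, the TRAP complex and signal peptidase, which move new proteins into the endoplasmic reticulum, 7 rose and 0 fell, with SEC61G at 3.70 and SEC61B at 3.60. Of 26 spliceosomal Sm and LSm genes, 8 rose and 2 fell (median 1.12, and 0.59 without control 1), with SNRPF at 2.80 and LSM8 at 2.14. Mitochondrial ribosomal protein genes had 25 up and 7 down of 77 (median 0.66, and 0.39 without control 1), with MRPS23 at 2.12 and MRPS26 at -1.76. Proteasome subunits had 11 up and 3 down of 37 (median 0.62, and 0.26 without control 1), with PSMA5 at 3.07 and PSMC1 at -2.17. Camera gave each of these 4 families an adjusted p between 0.000846 and 0.0107, against the adjusted p = 0.432 with an estimated correlation. The families that did not pass were zinc finger genes (camera adjusted p = 0.773), collagens (0.306), chaperonin subunits (0.0945), cytosolic tRNA synthetases (0.148), initiation factors (0.379) and tubulins (0.379).

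Of 42 genes with HIST symbols, 20 fell and 0 rose (median -1.68, and -1.10 without control 1). Of 117 small nucleolar RNA genes, 31 fell and 1 rose (median -0.94, and -0.63 without control 1), and all 7 SNAR genes fell (median -3.34, and -1.49 without control 1). The adjusted p = 0.432 with an estimated correlation held for these families too. Replication-dependent histone, small nucleolar and SNAR RNAs mostly lack a poly(A) tail, the feature on which the library kit primes.

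For the broad difference between control and knockdown libraries, control 1 alone was argued against as the source. Control 1 minus knockdown 1 correlated with control 2 minus knockdown 2 across genes at r = 0.593, with no library shared. GC content of the longest transcript as the whole cause was argued against by 2940 calls with GC offsets. These offsets did not use the 3' part that the libraries read, so GC content there was not tested as the whole cause. GC as a part stayed open, with Spearman's rho of -0.20 with the fold change (-0.21 for the last 500 nucleotides). Median GC was 45.6% in genes that rose and 55.6% in genes that fell. A few abundant genes as the whole cause would move every other gene one way, which was argued against by the 36.2% of other genes called by library size only that were lower in the knockdown (942 of 2602), whereas removing TERT and short RNA genes (3311 calls) moved the median fold change by only -0.0058 and tested nothing. A quality axis on which the controls also differ stayed open. In 84.7% of called genes control 2 lay between control 1 and the knockdown mean. Over all tested genes control 2 projected at 0.38 on the line from the knockdown mean (0) to control 1 (1). Deviations of control 1 alone also push that share up and this projection below 1, so neither value tests the axis. Control 1 minus control 2 correlated with the knockdown mean minus control 2 at -0.19 over all tested genes, between its bounds of -0.3 and -0.1. In the 3293 genes at log2 CPM 6 or more this correlation was -0.38, past the bound for a cause. Control 2 enters both differences, so its own deviations push this correlation upward. A first form, against the knockdown mean minus the control mean, gave -0.65 and met its bound of -0.5, and the test and bounds were replaced after that value was seen because deviations of control 1 alone push that correlation down. Library handling that differs between groups may therefore account for part of the difference and cannot be told apart from an effect of the guide, which stays open.

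The high TERT and short RNA counts of the controls were weighed next. Genomic DNA is an unlikely source, since SLC6A18 and SLC6A19, which lie near TERT, had 0 reads per 1000 TERT reads (0 against 673194, which allows up to 0.00446 per 1000). CLPTM1L, which also lies near TERT, had 1.25 reads per 1000 TERT reads in the controls (98 and 743 reads), and its log2 fold change was 1.86 (edgeR adjusted p = 0.0395), higher in the knockdown. A common source that raises SNAR-E and TERT in proportion was argued against by their ratio, which was 8.0 times higher in control 1 than in control 2. An RNA introduced with a vector, and a real difference in TERT expression between the cell populations, stayed open, because gene counts do not show where in TERT the reads lie. In the controls TERT stood at 89771 and 35177 CPM, above GAPDH at 21017 and 6094 CPM. How far these counts measure native TERT mRNA was not tested.

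The lower AKAP12 of the knockdown was set against the general spread between groups. Of 129 genes within 1 log2 CPM of AKAP12, 24 (18.6%) had a log2 fold change at or below -1.04, so a shift of this size may arise from that spread alone. An effect of the guide predicts a lower level too, and all 3 knockdown libraries were below both controls. These counts do not separate the explanations.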
